A study of Mus musculus with 14 samples.

How the data were processed

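RNA was measured on 14 Affymetrix Mouse Gene 2.0 ST arrays, 1 per sorted cell sample. Per the labels' protocols, the mice carried an EGFP and tamoxifen-inducible Cre cassette at Lgr5, with or without floxed Atg7 alleles. They received tamoxifen on 5 consecutive days and were killed 1 month later. Crypt cells with low CD24 were sorted into an EGFP high and an EGFP low gate, and 1 ng of total RNA per sample was amplified before hybridisation. The groups were 4 knockout and 4 wild-type EGFP low samples, and 3 knockout and 3 wild-type EGFP high samples, taken from the sample titles. A single sample is named by its group and the number in its title, as in WT-Low-411. The labels say that the samples came from individual mice. They do not say that the number in a sample title names the animal, so the numbers were not used to pair samples in the main fit.

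The deposited table holds log2 values, 1 per probe set and array, that the authors made with Affymetrix Expression Console and RMA, per the submitters' processing notes. RMA corrects the background, quantile normalizes the probes and summarises them per probe set. It can narrow large differences, and it assumes that most genes do not differ between arrays. The version of these tools and the grouping of probes into probe sets are not given in the sources used here. The deposited log2 values ran from 1.65 to 13.8, with array medians between 4.30 and 4.49. Arrays give no read depth, and the number of arrays limits the precision.

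The table has 25429 probe sets. The platform annotation lists 1 gene symbol for 24675 of them and several for 0. The remaining 754 were left out as unnamed, so some genes are not analysed here. Each gene had 1 probe set, so no rule for several probe sets per gene was needed. Genes were tested if their value was at or above the 40th percentile of an array on at least 3 arrays, which left 15873 genes.

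Group means were fitted over all 14 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 10 residual degrees of freedom and a prior of 4.54. Contrasts compared knockout with wild type within each gate and EGFP high with low within each genotype. A further contrast took the difference of the knockout effect between the gates. P-values are two-sided and adjusted with the Benjamini-Hochberg method over the 15873 genes, and a gene was called at adjusted p under 0.05. An error given as SE comes from this fit.

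Before the data were examined, 28 gene lists were fixed. They cover Lgr5 stem cell, reserve stem cell, Wnt target and Notch genes, and markers of enterocytes, goblet, Paneth, enteroendocrine and tuft cells, leukocytes and stroma. They also cover the cell cycle, DNA repair, NRF2 targets and other antioxidant enzymes, autophagy, mitophagy, lysosome and unfolded protein response. Further lists cover interferon, antigen presentation, inflammation, oxidative phosphorylation, glycolysis, apoptosis, dissociation stress and p53 target genes. The list of p53 target genes is labelled DNA damage checkpoint targets in the text and figures. Some lists share members, as Wnt targets do with Lgr5 stem cell markers. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01 between genes, adjusted over the 28 lists. Camera with an estimated correlation and limma's fry were run beside it. An interval over samples was taken from a linear model of a list's mean per array on the 4 groups, with 10 residual degrees of freedom. For each list the members that passed were also counted with p-values adjusted over the list alone.

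The genes named in the text follow a rule fixed at the same time. Among the genes it takes are Atg7, Lgr5, Olfm4, Ascl2 and Cdkn1a. In each of the 4 group comparisons it takes up to 10 called genes with the largest rise and 10 with the largest fall whose arrays do not overlap, filled up to 5 per direction by smallest p. For the difference between gates it takes the 5 smallest p, and for each list up to 4 called members, or 2 by smallest p where none was called. Predicted genes were left out of the ranking, except where a comparison called 5 genes or fewer.

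The fit was tested on simulated values for the 15873 genes with 200 changed genes per comparison. At a log2 change of 2, 97.1% of the changed genes were recovered for knockout against wild type in EGFP high cells, and 100% in EGFP low cells. At a log2 change of 1 these shares were 54.1% and 68.5%. For the difference of the knockout effect between the gates they were 82.8% at a log2 change of 2 and 27.7% at 1. Among the unchanged genes, 8 were called in EGFP high cells, 16 in EGFP low cells and 4 for that difference. The simulated noise was independent between genes. In a separate simulation with such noise both lists shifted by -0.4 were found in each of the 4 group comparisons, with 0 other lists. That simulation does not test lists whose members vary together.

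Alternatives fixed beforehand covered the prior, the groups in the fit, a block on the title number, 3 further normalizations, 2 other filters, array weights, a covariate for Y-linked signal, 2 other thresholds, the list tests, and leaving out each array. A pair of alternatives was chosen after seeing the data: leaving out the 2 arrays with the narrowest spread of values, and the SD of each array's values as a covariate.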

Results

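The arrays profiled crypt cells of mice in which Cre, active where Lgr5 is expressed, can remove Atg7, a gene needed to form autophagosomes. The EGFP high gate holds intestinal stem cells and the EGFP low gate their transit amplifying progeny, as the labels name them. There were 3 knockout and 3 wild-type samples of EGFP high cells, and 4 and 4 of EGFP low cells. The samples came from individual mice, and p-values of single genes rest on the spread between these samples. Camera's p-values for lists, with the preset correlation, rest mainly on the spread between genes.

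Atg7 was lower on each of the 7 knockout arrays than on any of the 7 wild-type arrays. In EGFP low cells its level was 5.89 ± 0.20 (SD, n = 4) in the knockout and 6.91 ± 0.43 (SD, n = 4) in wild type. In EGFP high cells it was 6.14 ± 0.23 (SD, n = 3) against 6.79 ± 0.04 (SD, n = 3). An exact permutation test stratified by gate, two-sided, gave p = 0.00143, the smallest its 1400 arrangements allow. That test shuffles each gate separately and treats all samples as independent. If the 3 title numbers found in both gates name mice, its p is too small. Within a gate the exact p was 0.0286 for EGFP low and 0.1 for EGFP high cells, again the smallest possible. Over all genes tested Atg7 was not called, with adjusted p = 0.166 in EGFP low and 0.208 in EGFP high cells. The sources used here do not say which exons were floxed, and the probe set can read exons outside the deleted part.

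**Figure D1:**
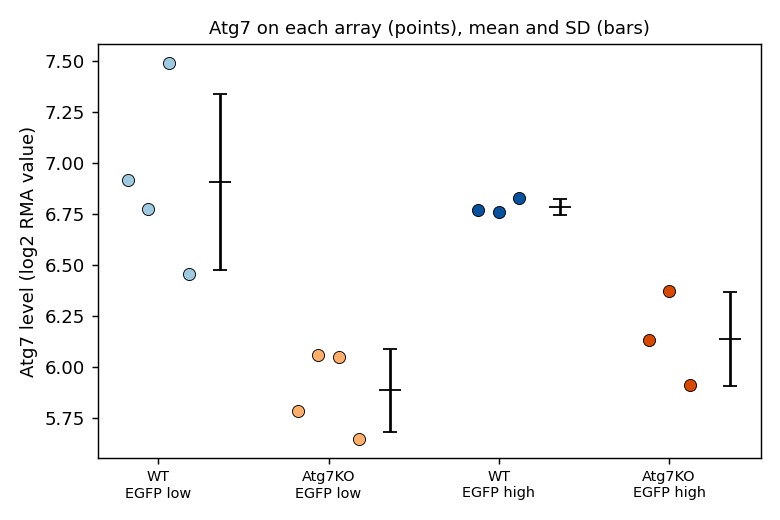
Atg7 level (log2 RMA value) on each array by genotype and gate, with the mean and SD of each group beside its points. The highest knockout array, at 6.37, lies below the lowest wild-type array, at 6.46.

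The spread of values differed between arrays. The SD of all log2 values on an array was 1.94 ± 0.04 (SD, n = 3) for knockout EGFP high samples and 2.04 ± 0.04 (SD, n = 3) for wild-type EGFP high samples. It was 2.02 ± 0.03 and 2.00 ± 0.07 for knockout and wild-type EGFP low samples (n = 4 each). The wild-type EGFP low sample WT-Low-411, with an SD of 1.90, stood apart on the second principal component. The first component held 29.7% of the variance and separated the gates. Y-linked genes were detected on 5 of the 14 arrays, in each group at least once.

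**Figure D2:**
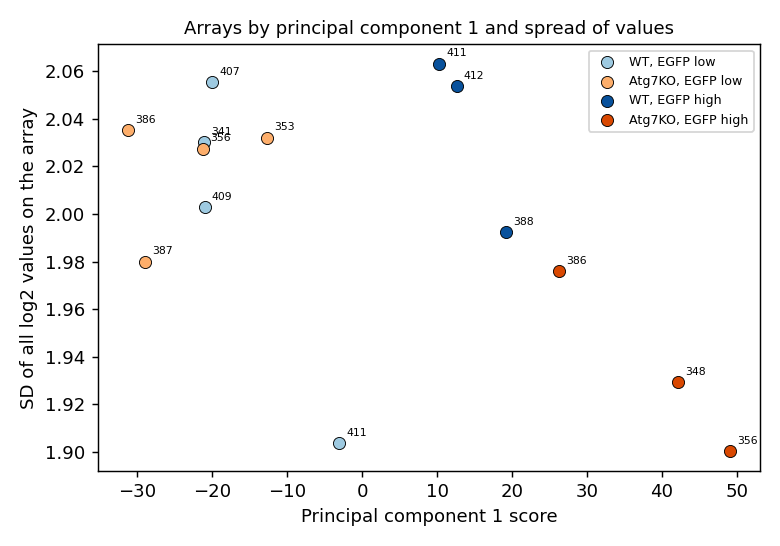
Each point is an array, placed by its score on principal component 1 and by the SD of its log2 values, coloured by group and labelled with the number in its title. Knockout EGFP high arrays lie at SDs of 1.90 to 1.98, and WT-Low-411 at 1.90.

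The first comparison asks how loss of Atg7 changes the stem cell gate. Goblet cell markers were lower as a list in knockout than in wild-type EGFP high cells, with a median log2 difference of -0.60 and 19 of 19 members lower (adjusted p = 0.457 with an estimated correlation). Their mean level was 7.08 in Atg7KO-High-356, 7.81 in Atg7KO-High-348 and 8.54 in Atg7KO-High-386, against 8.36 to 8.76 in wild type, and the median was -0.29 without Atg7KO-High-356 (adjusted p = 0.0136) and -0.99 without Atg7KO-High-386. Paneth cell markers were lower by a median of -0.57, with 15 of 16 members lower (adjusted p = 0.447 with an estimated correlation), or -0.35 without Atg7KO-High-356. Without the 2 arrays with the narrowest spread, Atg7KO-High-356 and WT-Low-411, both medians were the same as without the first alone. Enterocyte markers had a median of -0.49, with 25 of 26 lower (adjusted p = 0.476 with an estimated correlation). Their call rested on WT-High-388, at a mean enterocyte level of 8.04 against 6.95 and 7.36 in the other wild-type and 6.88 to 6.95 in the knockout samples, and without it the median was -0.17 (adjusted p = 0.217). Among goblet markers, Clca1, which encodes a secreted mucus protein, read 7.58 ± 1.16 against 9.36 ± 0.51 (SD, n = 3 each), and Atoh1, the transcription factor of secretory fate, 6.94 ± 0.71 against 7.99 ± 0.28. Among Paneth markers, Ang4, an antimicrobial ribonuclease, differed by -2.30 (SE 0.40), and Itln1, an intestinal lectin, by -2.20 (SE 0.50). Fabp1, a fatty acid binding protein of enterocytes, differed by -1.41 (SE 0.35). None of these members passed over all genes, while 4 goblet, 3 Paneth and 1 enterocyte marker fell when adjusted over the list alone, and 9, 7 and 8 had an unadjusted p under 0.05. Enteroendocrine markers had a median of -0.00 and were not called.

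The G2 and M phase and the S phase list were called lower too, both at adjusted p = 0.447 with an estimated correlation. All 29 tested G2 and M phase genes had negative differences, with a median of -0.48, and 16 fell when adjusted over the list alone, against 0 over all genes and 17 at an unadjusted p under 0.05. The mitotic kinases Ttk and Plk1 differed by -0.68 (SE 0.16) and -0.66 (SE 0.16). S phase genes had a median of -0.49, with 28 of 32 lower and 3 that fell adjusted over the list alone. With the array SD as a covariate, chosen after seeing the data, the S phase median was -0.07 and not called (adjusted p = 0.372), and that of G2 and M phase genes was -0.30 and called. With quantile normalization again the G2 and M phase median was -0.30 and with cyclic loess -0.24, both called, and those of S phase genes were -0.32 and -0.29. Without Atg7KO-High-356 or WT-High-411 the S phase median was -0.30 and -0.32, called in both cases. Slbp, the histone mRNA binding protein, differed by -0.61 (SE 0.14), and Rrm1, a subunit of ribonucleotide reductase, by -0.82 (SE 0.19).

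The other 9 lists called lower had adjusted p of 0.447 or 0.476 with an estimated correlation. Antigen presentation genes had a median of -0.58, and all 19 were lower, among them the peptide transporter Tap1 (-0.84, SE 0.27) and H2-DMb1 (-1.45, SE 0.49). Their mean level was 7.47 to 8.29 in knockout and 8.15 to 8.74 in wild-type samples. The groups overlapped, with Atg7KO-High-386 at 8.29 above WT-High-412 at 8.15. Interferon-stimulated genes had a median of -0.33, with Ifih1, a sensor of double-stranded RNA, at -0.71 (SE 0.16). Unfolded protein response genes (-0.34), other antioxidant enzymes (-0.33), glycolysis genes (-0.32), autophagy genes other than Atg7 (-0.22), DNA repair genes (-0.21), lysosomal genes (-0.20) and oxidative phosphorylation genes (-0.20) were the others. Atg3, the enzyme that works with Atg7 in lipid conjugation of LC3, differed by -0.64 (SE 0.14), and Pfkl, a glycolytic phosphofructokinase, by -0.92 (SE 0.18). Of the 14 called lists 0 hold with an estimated correlation, and 8 lost their call with the array SD as a covariate: the S phase list and 7 of these 9, antigen presentation and interferon-stimulated genes keeping theirs. Normalization and filter ended calls too. With quantile normalization again the lysosomal (-0.06, adjusted p = 0.365), DNA repair (-0.10), autophagy (-0.12) and antioxidant lists (-0.18) were not called, and glycolysis and unfolded protein response genes were called at -0.15 and -0.21. With cyclic loess 7 were not called, the lysosomal (-0.04), autophagy (-0.09), glycolysis (-0.10), oxidative phosphorylation (-0.12), DNA repair (-0.12), antioxidant (-0.14) and unfolded protein response lists (-0.19). A strict filter, a mean at or above the 60th percentile, ended the same 7 calls, at medians of -0.34 to -0.20, with interferon-stimulated genes called at -0.52, and without a filter glycolysis genes were called at -0.12. Leaving out single samples also ended calls. Without WT-High-411 the interferon (median -0.29, adjusted p = 0.164), unfolded protein response (-0.21), antioxidant (-0.20), DNA repair (-0.18), oxidative phosphorylation (-0.16) and glycolysis lists (-0.27) were not called. Without Atg7KO-High-348 the interferon (-0.24), antioxidant (-0.27), lysosomal (-0.18), oxidative phosphorylation (-0.20) and glycolysis lists (-0.21) were not, and without Atg7KO-High-356 the interferon (-0.28), unfolded protein response (-0.23), DNA repair (-0.17) and glycolysis lists (-0.17). The interferon, DNA repair and glycolysis lists were not called without the 2 narrowest arrays either. Without WT-High-412 lysosomal (-0.17) and glycolysis genes (-0.36), and without Atg7KO-High-386 antioxidant enzymes (-0.20), were not called either. Called still, the interferon median was -0.52 without Atg7KO-High-386, and that of autophagy genes -0.14 without WT-High-388. Lists that were not called included Lgr5 stem cell markers, with a median of 0.06, Wnt targets (0.02) and DNA damage checkpoint targets (0.07). Medians of the other lists not called were 0.20 for reserve and regenerative stem cell markers, -0.11 for Notch genes, -0.17 for NRF2 targets, -0.17 for mitophagy receptors, -0.24 for inflammatory and antimicrobial genes, -0.14 for apoptosis genes and 0.00 for dissociation stress genes. Tuft cell markers (-0.23), leukocyte markers (-0.06) and stromal markers (0.10) were not called either. Lgr5 itself differed by 0.09 (SE 0.35) and Olfm4 by 0.05 (SE 0.23). Cdkn1a, the cell cycle inhibitor p21, read 6.58 ± 0.48 in the knockout and 7.59 ± 0.06 in wild type (SD, n = 3 each; limma adjusted p = 0.133).

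Over single genes, limma called 2 of 15873. Gm12292, a long noncoding RNA, rose by 2.01 (SE 0.16, adjusted p = 7.08e-05), and Pxdn, a peroxidase of the extracellular matrix, fell by 1.39 (SE 0.20, adjusted p = 0.0427). Without Atg7KO-High-356, Atg7KO-High-348, WT-High-388 or WT-High-411 the adjusted p of Pxdn by limma was 0.0739, 0.140, 0.115 and 0.358, at differences of -1.44, -1.41, -1.25 and -1.33. Pxdn was not called either with the 2 groups alone in the fit, median centring, no filter, the Y-linked covariate or without the 2 narrowest arrays (highest adjusted p by limma 0.0929). At an unadjusted p under 0.05 there were 2519 genes, 950 higher and 1569 lower, where 794 would be expected by chance. Array weights raised the count of called genes to 703, and leaving out Atg7KO-High-386 raised it to 43. The narrower spread on knockout EGFP high arrays went with lower values of highly expressed genes, with a median of -0.24 in the fifth with the highest level and 0.13 in the lowest.

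**Figure D3:**
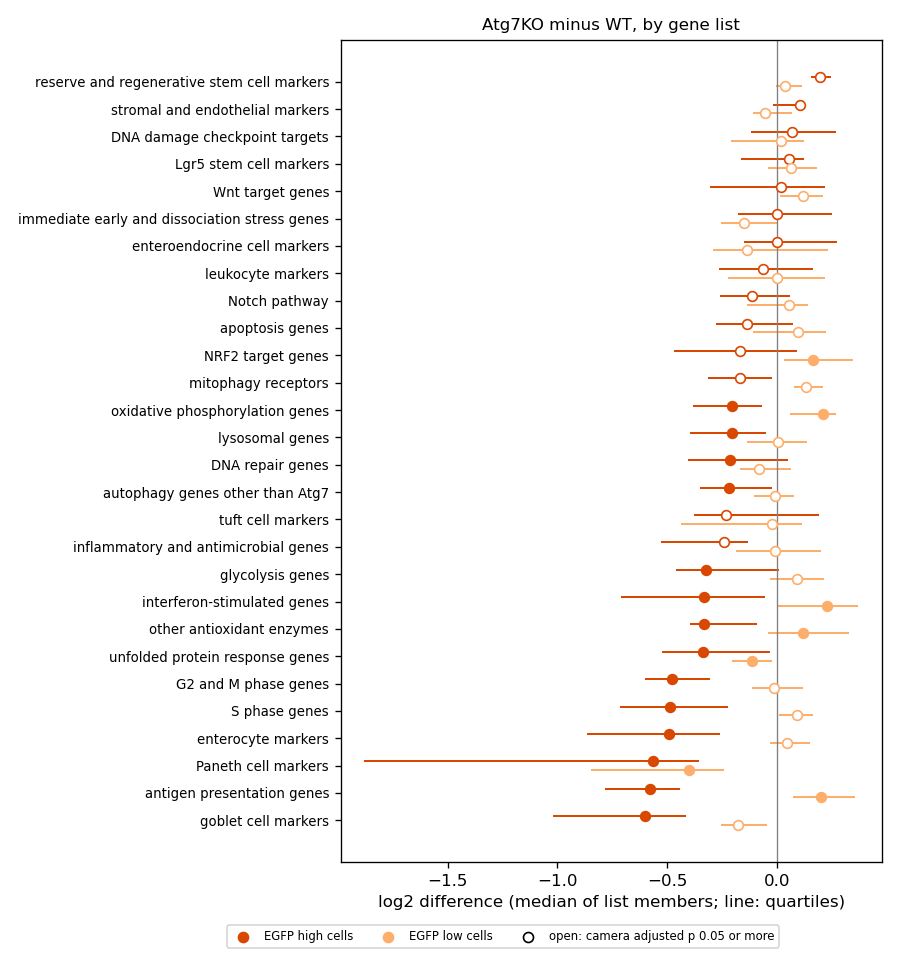
Median log2 difference between knockout and wild type for each of the 28 gene lists in EGFP high (dark) and EGFP low (light) cells, with lines for the quartiles of list members and filled points where camera's adjusted p is under 0.05. In EGFP high cells goblet markers lie lowest, at -0.60, while in EGFP low cells oxidative phosphorylation genes lie at 0.21.

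The same question in EGFP low cells gave smaller differences. The 7 lists called here each had adjusted p = 0.758 with an estimated correlation, and fry called 0. Paneth cell markers were lower as a list, with a median of -0.40 and 14 of 16 members lower (adjusted p = 0.758 with an estimated correlation), and Ang4 differed by -1.43 (SE 0.35). WT-Low-411, the sample that stands apart, had the highest mean Paneth level, 10.6, and without it the median was -0.15 (adjusted p = 0.0644), or -0.20 with array weights (adjusted p = 0.0518). Without both narrowest arrays it was -0.15 and called (adjusted p = 0.0442). Unfolded protein response genes were lower by a median of -0.11 (adjusted p = 0.758 with an estimated correlation), with Edem1, a factor of protein degradation in the endoplasmic reticulum, at -0.45 (SE 0.15). Their median was -0.08 without Atg7KO-Low-356 (adjusted p = 0.441) and -0.05 without WT-Low-409 (adjusted p = 0.245), and without Atg7KO-Low-353 or WT-Low-411 it was -0.17 and -0.18 and called. Oxidative phosphorylation genes were higher, with a median of 0.21 and 27 of 33 members higher (adjusted p = 0.758 with an estimated correlation), or 0.13 without WT-Low-411 or both narrowest arrays. The median was 0.11 with quantile normalization again or cyclic loess and 0.12 with array weights, called in each case. Cox8a, a subunit of cytochrome c oxidase, differed by 0.34 (SE 0.14) and Uqcrfs1, the iron-sulfur subunit of complex III, by 0.40 (SE 0.18).

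NRF2 target genes were higher by a median of 0.16 (adjusted p = 0.758 with an estimated correlation), with the glutathione transferases Gstm3 and Gstm2 at 0.77 (SE 0.31) and 0.60 (SE 0.24). WT-Low-411 had the lowest mean NRF2 target level, 7.01 against 7.30 to 7.55 in the other wild-type EGFP low samples, and without it the median was 0.09 and not called (adjusted p = 0.246). Without Atg7KO-Low-356 it was 0.11 and without WT-Low-407 it was 0.25, both called. With quantile normalization again it was 0.07, and with cyclic loess or the array SD as a covariate 0.08, called in each case, and without the 2 narrowest arrays it was 0.09 and not called (adjusted p = 0.233). Other antioxidant enzymes had a median of 0.12 (adjusted p = 0.758 with an estimated correlation), and 2 of 23 rose adjusted over the list alone, where Glrx5 and Prdx4, both at 0.68, had the smallest p. Their mean level in WT-Low-411 was 6.74 against 6.93 to 7.08, and without that sample the list was not called, at a median of 0.16 (adjusted p = 0.103), while without Atg7KO-Low-387 it was called at 0.22. It was called at 0.06 with quantile normalization again, 0.07 with cyclic loess and 0.27 with the strict filter, and not called without the 2 narrowest arrays (adjusted p = 0.121). With array weights neither list was called, at medians of 0.06 and 0.14 (adjusted p = 0.211 and 0.0672). Interferon-stimulated genes (0.23) and antigen presentation genes (0.20) were higher as lists, with H2-DMb1 at 1.41 (SE 0.43), both at adjusted p = 0.758 with an estimated correlation. Without Atg7KO-Low-387, Atg7KO-Low-386 or WT-Low-407 neither was called, with medians of 0.16, 0.20 and 0.21 for interferon-stimulated and 0.11, 0.12 and 0.10 for antigen presentation genes, whose median was 0.42 and called without Atg7KO-Low-356. Antigen presentation genes were not called with cyclic loess (0.19, adjusted p = 0.0662), nor interferon-stimulated genes with the strict filter (0.21, adjusted p = 0.0547). Lgr5 stem cell markers (0.06), S phase genes (0.09), G2 and M phase genes (-0.01) and autophagy genes (-0.01) were not called. Among reserve stem cell markers, which were not called as a list, Anxa3 (1.06, SE 0.25) and Hopx (0.56, SE 0.17) had the smallest p, and 2 of 14 rose adjusted over the list alone. Cdkn1a differed by -0.01 (SE 0.21).

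A single gene was called in EGFP low cells. Rnf5, a ubiquitin ligase of the endoplasmic reticulum, rose by 1.72 (SE 0.21, adjusted p = 0.013). Without Atg7KO-Low-353, Atg7KO-Low-387, Atg7KO-Low-386 or WT-Low-407 its adjusted p by limma was 0.0881, 0.0853, 0.0726 and 0.0555, at differences of 1.66, 1.67, 1.73 and 1.77. An unadjusted p under 0.05 was reached by 1152 genes, against 794 expected by chance. With the groups of the comparison alone in the fit (adjusted p of Rnf5 0.233), 0 genes were called, and without the 2 narrowest arrays Rnf5 was not called (1.55, adjusted p = 0.0717).

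The third comparison, EGFP high against EGFP low cells of wild type, shows what the gates separate. In wild type 193 genes were higher and 194 lower in EGFP high cells. Lgr5 rose by 3.52 (SE 0.33, adjusted p = 0.000247), from 5.50 ± 0.67 (SD, n = 4) to 9.02 ± 0.31 (SD, n = 3). Of 28 tested Lgr5 stem cell markers 23 rose, or 25 when adjusted over the list alone, with a median of 1.11. They included Igfbp4 (1.96), Msi1 (1.49), Rgmb (1.34), Olfm4 (1.05) and Ascl2 (0.78). Without WT-High-388, WT-High-411 or WT-High-412 Olfm4 was not called (highest adjusted p by limma 0.0835), and Ascl2 was not called without any sample other than WT-High-388 (highest 0.245). Ascl2 was not called either with the 2 groups alone in the fit, median centring, no filter, the Y-linked covariate, the array SD as a covariate or without the 2 narrowest arrays. Of 20 Wnt target genes 10 rose, or 11 adjusted over the list alone, among them Axin2 (1.64), Rnf43 (1.78) and Sox9 (1.08). These 2 lists kept their call with an estimated correlation, at adjusted p = 0.00549 and 0.00586, and the median of Wnt targets was 0.66, or 1.19 with the strict filter. The 2 lists share many members, among them Lgr5, Ascl2, Axin2, Rnf43 and Sox9, so they are not separate results. The Notch list was not called (median 0.19, adjusted p = 0.0561), and in it the receptor Notch1 (1.31), Dtx4 (1.01) and Hes1 (0.87) rose, while Atoh1 fell by 1.39. Of these, Dtx4 was not called without WT-High-412 (adjusted p by limma 0.0602), Hes1 without any single EGFP high sample (highest 0.0834), and Atoh1 without WT-Low-341, WT-Low-409 or any single EGFP high sample (highest 0.126).

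Goblet and enteroendocrine markers were lower in EGFP high cells of wild type, at adjusted p = 0.081 and 0.0824 with an estimated correlation. For goblet markers 13 of 19 fell, or 19 adjusted over the list alone, with a median of -1.46 and Clca1 at -2.18 (SE 0.40). For enteroendocrine markers 8 of 21 fell, or 19 adjusted over the list alone, with a median of -1.72. They included the hormone genes Gip (-3.23), Tac1 (-2.46) and Cck (-2.28). Reg4 (-2.24) and Nupr1 (-2.18), which are in the Paneth list, and the enterocyte keratin Krt20 (-1.73) fell too. The Paneth list itself had a median of only -0.43. Of these 7 genes only Cck kept its call without each single sample. Clca1 lost it without WT-High-411 or WT-High-412 (highest adjusted p by limma 0.0750), Gip and Reg4 without WT-Low-409, WT-High-388 or WT-High-412 (0.0961 and 0.0886), Tac1 and Nupr1 without WT-Low-409 or any single EGFP high sample (0.103 and 0.0853), and Krt20 without any sample other than WT-Low-411 or WT-High-388 (0.178), without a filter or with the array SD as a covariate. Unfolded protein response genes had a median of -0.38 (adjusted p = 0.229 with an estimated correlation), with 3 of 27 that fell, Edem1 (-0.93), Dnajb9 (-0.73) and Dnajc3 (-0.83). Edem1 was not called without WT-High-412 (adjusted p by limma 0.0523), Dnajb9 without WT-Low-409 or WT-High-388 (highest 0.0792) or with the 2 groups alone in the fit, and Dnajc3 without any single sample (highest 0.158) or with the Y-linked covariate. S phase genes (0.49), DNA repair genes (0.36), G2 and M phase genes (0.26) and antigen presentation genes (0.50) were higher as lists, with adjusted p of 0.358, 0.103, 0.358 and 0.358 with an estimated correlation. Enterocyte markers (-0.40), Paneth markers (-0.43) and dissociation stress genes (-0.30) were lower as lists, at adjusted p of 0.482, 0.385 and 0.596 with an estimated correlation. Without WT-High-411 the enterocyte median was -0.20 and not called (adjusted p = 0.130), and with the array SD as a covariate it was -0.23 and called. The Paneth median was -0.26 without WT-Low-411 or both narrowest arrays and -0.28 with array weights, called in each case. Dissociation stress genes were not called without WT-Low-407 (-0.12), WT-Low-409 (-0.30), WT-High-388 (-0.25) or WT-High-412 (-0.29), nor with median centring (-0.35), no filter (-0.28) or the Y-linked covariate (-0.23). With the title number as a random block they were not called either (-0.30, adjusted p by camera 0.0557).

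Beyond the lists, the largest rises in wild type included the urea transporter gene Slc14a1 (1.73), Emp2 (1.72), Pik3ap1 (1.72), Bex1 (1.59) and Edn1, which encodes endothelin 1 (1.57). The largest falls were Mptx1 (-3.92), Afp (-3.84), the neurotensin gene Nts (-3.51), Gip, Gsdmc2 (-2.87), Serpina1b (-2.82) and Sytl2 (-2.65). Emp2 was not called without any single sample (highest adjusted p by limma 0.137), Bex1 without any other than WT-Low-407 (0.150), Slc14a1 without WT-High-411 or WT-High-412 (0.0693), Pik3ap1 without WT-High-412 (0.0645) and Edn1 without WT-High-388 (0.0526). Without a filter or with the array SD as a covariate neither Emp2 nor Bex1 was called, and with the 2 groups alone in the fit or without the 2 narrowest arrays Bex1 was not. Of the falls, Nts and Serpina1b were not called without WT-Low-407, WT-Low-409 or any single EGFP high sample (highest 0.125 and 0.105), and Gsdmc2 without WT-High-388 or WT-High-412 (0.0902). Cdkn1a fell by 1.34 (SE 0.23). Of the 35 genes named for this comparison 13 kept their call without each single sample. Without WT-Low-407, WT-Low-409, WT-High-388, WT-High-411 and WT-High-412 there were 245, 158, 146, 119 and 103 called genes, and array weights gave 1201.

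In the knockout 1734 genes differed between the gates, 711 higher and 1023 lower in EGFP high cells. Without Atg7KO-High-356, Atg7KO-High-348 and Atg7KO-Low-386 there were 781, 851 and 1111, and with the 2 groups alone in the fit 1027. Lgr5 rose by 3.32 (SE 0.33, adjusted p = 0.000138), and Olfm4 by 1.08 (SE 0.21). Of the Lgr5 stem cell markers 21 of 28 rose, or 25 adjusted over the list alone, with a median of 1.08, and the list kept its call with an estimated correlation, at adjusted p = 0.0293. Of 20 Wnt target genes 6 rose, or 9 adjusted over the list alone, with a median of 0.38 (0.94 with the strict filter), and the adjusted p was 0.0732 with an estimated correlation. Goblet markers fell in 18 of 19 cases (adjusted p = 0.133 with an estimated correlation), with a median of -1.98 and Clca1 at -3.54 (SE 0.40), Zg16 at -3.49 and S100a6 at -3.07. Enteroendocrine markers fell in 14 of 21 cases, with a median of -1.70, and enterocyte markers in 12 of 26, with a median of -0.96 and the brush border enzymes Sis and Enpep at -2.79 and -2.68. With an estimated correlation these lists had adjusted p of 0.274 and 0.324. The enteroendocrine median was -1.06 without Atg7KO-High-356 or both narrowest arrays and the enterocyte median -0.62 without Atg7KO-Low-387, both called.

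A further 8 lists were called between the gates in the knockout, none of them with an estimated correlation. NRF2 targets fell in 7 of 31 cases, or 10 adjusted over the list alone (adjusted p = 0.271 with an estimated correlation), among them Nqo1 (-1.71), Gsta4 (-1.84) and Ugdh (-1.27). Their median was -0.42, -0.28 without Atg7KO-Low-356 and -0.17 with the array SD as a covariate, called in each case. Unfolded protein response genes fell in 8 of 27 cases, or 17 adjusted over the list alone (adjusted p = 0.274 with an estimated correlation), with Manf at -1.19 and Dnajc3 at -1.14. Oxidative phosphorylation genes fell in 5 of 33 cases, with Sdhb at -0.80, and interferon-stimulated genes in 5 of 32, with Ifih1 at -0.89 and Zbp1 at -1.98 (adjusted p = 0.393 and 0.416 with an estimated correlation). Of the glycolysis genes Pfkp (-1.94) and Ldha (-0.63) fell (adjusted p = 0.271 with an estimated correlation). Genes of the Paneth list fell in 6 of 16 cases, with Reg4 at -3.38 against a list median of -0.64, and other antioxidant enzymes in 2 of 23 (adjusted p = 0.324 and 0.287 with an estimated correlation). DNA repair genes rose in 6 of 55 cases, among them Prkdc (0.83) and Brca2 (0.79), and their adjusted p was 0.393 with an estimated correlation. With the array SD as a covariate the oxidative phosphorylation, glycolysis and antioxidant lists were not called, at medians of -0.14, -0.04 and -0.16, and without Atg7KO-High-348 antioxidant enzymes were not called (-0.28, adjusted p = 0.0602). Antioxidant enzymes were not called with quantile normalization again (-0.25), cyclic loess (-0.22) or the strict filter (-0.32) either. Called still, the medians were -1.24 for Paneth markers with the array SD as a covariate (-0.64 without it), -0.17 for oxidative phosphorylation genes with cyclic loess (-0.28 without it), 0.13 for DNA repair genes with the strict filter (0.22 with the usual one) and -0.33 for interferon-stimulated genes without a filter (-0.50 with it). The receptor Notch1 rose by 1.45 and Cdkn1a fell by 2.33 (SE 0.23). The largest rises beyond the lists included Kcnq1ot1 (2.62), Angpt2 (2.34), Myo9a (2.30) and Clca3a2 (2.19), and the largest falls Afp (-4.14), Mptx1 (-3.79) and Scin (-3.50). Of the 29 genes named for this comparison 25 kept their call without each single sample. Ugdh lost it without Atg7KO-High-356 (adjusted p by limma 0.0799), Zbp1 without Atg7KO-High-356 or Atg7KO-High-348 (highest 0.0889), Ldha without Atg7KO-Low-387, Atg7KO-Low-386, Atg7KO-High-356 or Atg7KO-High-348 (0.0911), and Brca2 without Atg7KO-Low-387, Atg7KO-Low-386, Atg7KO-High-356 or Atg7KO-High-386 (0.0844). With the array SD as a covariate Enpep, Ugdh, Manf, Sdhb, Ldha, Prkdc and Brca2 were not called, and without the 2 narrowest arrays Ugdh, Zbp1, Ldha and Brca2 were not. Ldha was not called with quantile normalization again or cyclic loess, nor Brca2 with the 2 groups alone in the fit.

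**Figure D4:**
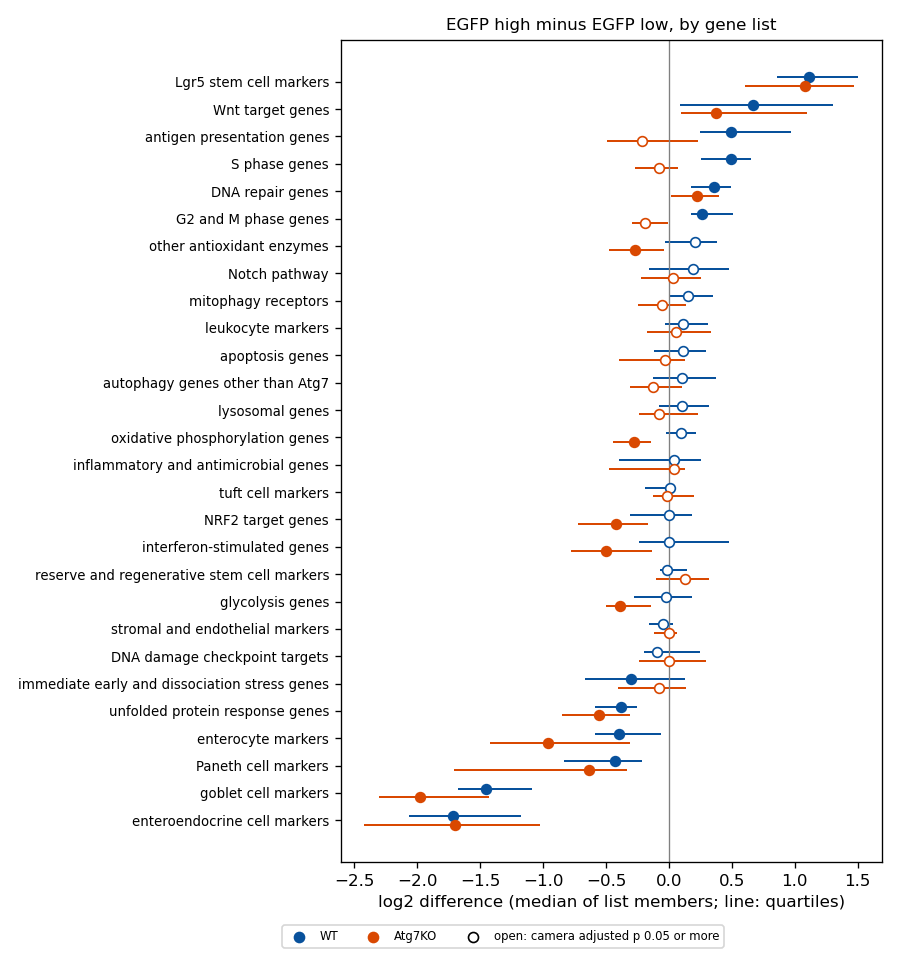
Median log2 difference between EGFP high and EGFP low cells for each of the 28 gene lists in wild type (blue) and knockout (orange), with lines for the quartiles of list members and filled points where camera's adjusted p is under 0.05. Lgr5 stem cell markers lie at 1.11 in wild type and 1.08 in the knockout, and goblet markers at -1.46 and -1.98.

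Of the genes higher in EGFP high cells, 92 were called in both genotypes, where independent lists would share 8.65. Of those lower, 145 were shared, against 12.5, and 1 gene was called in opposite directions. The 2 comparisons have no array in common, but the fit gives each gene the same estimate of spread in both. Genes with a small spread can therefore be called in both more often than independent lists allow. Across genes, which are not independent replicates, the differences between gates had a Pearson r of 0.46 between genotypes. The Spearman correlation was lower, at 0.27, and 56.6% of genes had the same sign in both genotypes. With the array SD as a covariate, chosen after seeing the data, 495 genes were called in the knockout and 314 in wild type.

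The last comparison tests whether the knockout effect differs between the gates. A single gene was called, Gm12292, with a knockout effect 2.33 higher (SE 0.22, adjusted p = 0.00039) in EGFP high than in EGFP low cells. Rnf5 had a difference of -2.18 (SE 0.32, adjusted p = 0.0593), and 2225 genes had an unadjusted p under 0.05. With an estimated correlation 0 of the 10 lists called by the preset test were called, at adjusted p of 0.46 or 0.649. As lists, antigen presentation genes (median -0.82), S phase genes (-0.57), enterocyte markers (-0.55), G2 and M phase genes (-0.47), goblet markers (-0.45) and interferon-stimulated genes (-0.45) had a lower knockout effect in EGFP high cells. So had oxidative phosphorylation genes (-0.43), other antioxidant enzymes (-0.41), NRF2 targets (-0.40) and glycolysis genes (-0.16). Adjusted over the list alone, 7 antigen presentation genes and 3 G2 and M phase genes passed, and 0 of either over all genes. With the array SD as a covariate the S phase (-0.13), goblet (-0.30), oxidative phosphorylation (-0.10), antioxidant (-0.08), NRF2 (-0.06) and glycolysis lists (-0.11) were not called, and G2 and M phase genes were called at -0.29. With quantile normalization again the medians of the S phase, G2 and M phase and oxidative phosphorylation lists were -0.34, -0.25 and -0.23, and with cyclic loess -0.32, -0.21 and -0.20, with -0.23 for antioxidant enzymes, called in each case. Enterocyte markers lost their call without WT-High-388 (-0.25, adjusted p = 0.204) or Atg7KO-Low-387 (-0.40, adjusted p = 0.0723) and with array weights (-0.25, adjusted p = 0.107), and goblet markers without Atg7KO-High-356 (-0.26, adjusted p = 0.574), WT-High-388 (-0.46), Atg7KO-Low-353 (-0.38) or WT-Low-407 (-0.38), without the 2 narrowest arrays (-0.15, adjusted p = 0.678), and with cyclic loess (-0.34, adjusted p = 0.0699) or the strict filter (-0.45, adjusted p = 0.149). Glycolysis genes lost theirs without Atg7KO-Low-353 (-0.17), WT-Low-411 (-0.12) or Atg7KO-High-356 (-0.19), without the 2 narrowest arrays (-0.18) and with the strict filter (-0.54). Their median was -0.40 without WT-High-388 and between -0.26 and -0.24 without WT-Low-407, WT-Low-409, Atg7KO-High-348 or WT-High-411, called in each case. Called too, the goblet median was -0.71 without Atg7KO-Low-356 and -1.0 without Atg7KO-High-386, the S phase median -0.33 without Atg7KO-High-356 and the NRF2 median -0.23 without WT-Low-411. Without the 2 narrowest arrays the S phase (-0.36), oxidative phosphorylation (-0.27), antioxidant (-0.25) and NRF2 medians (-0.20) were called. H2-DMb1 had the largest difference among the antigen presentation genes the rule names, at -2.86 (SE 0.65, adjusted p = 0.176). Across genes the knockout effects in the 2 gates had a Pearson r of -0.13.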

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

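Tests chosen only after the result was seen were the comparisons of goblet with enteroendocrine markers and of G2 and M phase genes over samples, those with the array SD as a covariate, and both tests of the count of genes that differ between the gates.

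Gm12292, a long noncoding RNA, differed in its knockout effect between the gates, by 2.33 on the log2 scale. The tests of the same difference picked out 10 gene lists with a lower knockout effect in EGFP high cells, of which 0 were called with an estimated correlation (adjusted p = 0.46 or 0.649) or by fry. Their medians were -0.82 for antigen presentation genes, -0.57 for S phase genes, -0.55 for enterocyte markers, -0.47 for G2 and M phase genes, -0.45 for goblet markers and -0.45 for interferon-stimulated genes. Oxidative phosphorylation genes stood at -0.43, other antioxidant enzymes at -0.41, NRF2 targets at -0.40 and glycolysis genes at -0.16. Of 100 drawn splits by genotype within each gate, 12 gave as many genes as the real count of 1, with up to 87 in another split, and 24 gave as many lists as the real count of 10, with up to 14. Chance is not excluded for either count.

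The first pattern weighed is the lower gene lists in knockout EGFP high cells. Of the 14 called lists, 11 had a median below the 2.5th percentile of random lists matched on mean level. The random lists hold genes drawn independently, while members of a list can vary together, and the 14 were picked from these same values. The test therefore does not decide whether the narrower spread of values on those arrays is the whole explanation. Of these 11 lists, 6 kept their call with the array SD as a covariate. Of the 8 lists that lost it, autophagy, lysosomal and oxidative phosphorylation genes lay within the matched range, and for these 3 the spread may account for the difference, while for the other 5 (S phase, DNA repair, other antioxidant, unfolded protein response and glycolysis genes, with medians of -0.07, -0.03, -0.03, -0.16 and -0.03 under the covariate) it cannot be told apart from an effect of genotype. A smaller share of all differentiated cells would lower their markers alike, and this cannot be told apart from a change in single cell types: the enteroendocrine minus goblet mean per array was higher in the knockout by 0.72 (95% interval over samples 0.10 to 1.34), but without 1 array the interval reached 0 in 4 of 6 cases, with differences of 0.50 without WT-High-388 to 0.92 without WT-High-411. It would not lower cell cycle genes. The mean of G2 and M phase genes per array differed by -0.46 (95% interval over samples -0.72 to -0.19, and below 0 without any 1 of the 6 arrays). That interval makes no allowance for the narrower spread. Random lists matched to these genes on mean level had a median of -0.23 (central 95% -0.37 to -0.095), against -0.48 for the list. With part of the fall shared by genes of like level, the test on the mean does not decide. An effect of genotype stays open, and the 6 samples make too few splits for a share under 0.05, with 14 lists and 2 genes in the real split and at most 12 lists and 0 genes in another, both real counts being reached by 1 of the 10 splits.

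The second pattern weighed is that 1734 genes differed between the gates in the knockout, 711 higher and 1023 lower, against 193 higher and 194 lower in wild type. Without WT-Low-411, which stands apart, the wild-type count was 343. Leaving out any 1 wild-type sample lowered this count, to between 103 and 343. The test therefore cannot tell whether WT-Low-411 accounts for the pattern. The knockout count was 781 without Atg7KO-High-356, 851 without Atg7KO-High-348 and 1111 without Atg7KO-Low-386. The knockout count was 4.48 times the wild-type count, 3.87 times after quantile normalization, 2.75 times with the 2 groups alone in the fit, 1.58 times with the array SD as a covariate and 1.43 times with array weights (1723 against 1201 genes). The narrower spread on knockout EGFP high arrays and an effect of genotype therefore cannot be told apart, because that spread goes with the group. Other splits of the samples by gate gave at most 7 genes in wild type and 505 in the knockout, and only the real split, 1 of 35 in each genotype, reached the observed counts.

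Of the 35 splits of the wild-type samples, 10 gave as many as the 12 gene lists called between the gates, with up to 17. In the knockout 5 of 35 gave as many as 13, with up to 14. Each other knockout split that did so set EGFP low samples alone against a group with all EGFP high samples. Some of the wild-type splits did likewise, while others mixed the gates. Splits of the first kind keep part of the gate contrast, so the knockout count does not decide. Chance is not excluded for these counts. In EGFP low cells, 5 of 35 splits by genotype gave as many called genes as the real count of 1, with up to 6, and 17 gave as many lists as the real count of 7, with up to 14. Chance is not excluded there either.

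A single sample lay far from the other 3 of its group in 28 of 508 groups of 4 values checked, where chance alone gives about 25.4. In each, the gap to the nearest sample over the range of the group was above Dixon's critical value for 4 samples. The SD of all values of Atg7KO-Low-387 had a ratio of 0.860. In Atg7KO-Low-356 the ratio was 0.846 for Atg4b, 0.854 for Cenpf, 0.962 for Heyl, 0.844 for Nts, 0.849 for Spdef and 0.844 for Sytl2. In Atg7KO-Low-353 it was 0.869 for Gstm2, 0.955 for Habp2 and 0.856 for Scai. In Atg7KO-Low-387 it was 0.898 for Gsdmc2, 0.909 for Sesn3 and 0.830 for the mean of G2 and M phase genes. In Atg7KO-Low-386 it was 0.952 for Pax4, 0.894 for Prrg2, 0.830 for Txnrd1, 0.834 for the mean of tuft cell markers and 0.942 for the mean of stromal and endothelial markers. In WT-Low-411 it was 0.916 for Axin2, 0.860 for Casp4, 0.831 for Ccnd1, 0.852 for Iigp1, 0.851 for Rad23b and 0.928 for Rmrp. In WT-Low-341 it was 0.911 for Gpx3, 0.914 for Kctd12, 0.965 for Tnfaip8l1 and 0.865 for Vim.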

How the results depend on the processing

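The alternatives that leave out the 2 arrays with the narrowest spread and that use the array SD as a covariate were chosen after seeing the data. Counts of called genes are given in the order knockout against wild type in EGFP high cells (2), in EGFP low cells (1), between gates in wild type (193 higher and 194 lower), in the knockout (1734), and for the difference between gates (1). The first count was 5 with the 2 groups alone in the fit, 1 with median centring, no filter, the strict filter or the Y-linked covariate, 703 with array weights, 12 at adjusted p under 0.1, and 1188 at unadjusted p under 0.05 with 1.5-fold. The second was 0 with the 2 groups alone or without the 2 narrow arrays, and 375 at unadjusted p with 1.5-fold. The third was 1201 with array weights (where the fourth was 1723), 696 at adjusted p under 0.1 and 1267 at unadjusted p with 1.5-fold. The fourth was 1027 with the 2 groups alone, 1110 without the narrow arrays, 495 with the array SD as a covariate, 2894 at adjusted p under 0.1, and 2544 at unadjusted p with 1.5-fold. The fifth was 2 with the random replicate block, median centring, the strict filter, array weights or adjusted p under 0.1, and 1770 at unadjusted p with 1.5-fold. The cause of these moves was not tested, apart from the looser thresholds. Array weights gave WT-High-412 a weight of 3.27 and WT-Low-411 a weight of 0.367. Leaving out 1 sample gave 1 to 43 genes for the first count (43 without Atg7KO-High-386, 1 without Atg7KO-High-348, WT-High-388 or WT-High-411). The second ranged from 0 (without Atg7KO-Low-353, Atg7KO-Low-386, Atg7KO-Low-387 or WT-Low-407) to 2 (without WT-Low-341 or WT-Low-409). The third ranged from 103 to 343, with 245 and 158 without WT-Low-407 and WT-Low-409, and 146, 119 and 103 without WT-High-388, WT-High-411 and WT-High-412. The fourth ranged from 781 to 1742, with 781 and 851 without Atg7KO-High-356 and Atg7KO-High-348 and 1111 without Atg7KO-Low-386. The fifth ranged from 1 to 4, with 4 without WT-Low-341 and 3 without Atg7KO-High-386. Of the called genes, Gm12292 kept its call in 18 of 18 alternatives in EGFP high cells, Pxdn in 8 of 17 and Rnf5 in 14 of 20. Called lists numbered 14, 7, 12, 13 and 10 in the same order. With an estimated correlation they numbered 0, 0, 2, 1 and 0, and with fry 0, 0, 7, 11 and 0. In EGFP high cells the list count was 11 with quantile normalization, 7 with cyclic loess, 8 with the strict filter and 6 with the array SD as a covariate, in EGFP low cells 4 with array weights, and for the difference between gates 5 with the array SD as a covariate. Leaving out 1 sample gave 8 to 16, 4 to 9, 11 to 13, 13 to 15 and 8 to 11 lists. Goblet, Paneth, G2 and M phase and antigen presentation lists kept their call in EGFP high cells in 18 of 18 alternatives with the preset correlation, with medians from -0.99 to -0.29, -0.77 to -0.35, -0.54 to -0.24 and -0.78 to -0.41. With the array SD as a covariate the median of lysosomal genes turned to 0.0738 and that of oxidative phosphorylation genes to 0.0257, neither called. The title number is shared by 3 pairs of samples from both gates. Their deviations from the group means correlated at 0.11 and 0.18 for both knockout pairs and -0.04 for the wild-type pair, and Y-linked signal agreed within all 3 pairs. Both samples of each knockout pair correlated best with their own number and those of the wild-type pair did not, so by the rule that every pair must exceed 0.1 the samples are treated as sharing only a number. With the number as a random replicate block (consensus correlation 0.0732) the counts between gates were 445 and 1965. A fixed replicate block over the 2 knockout pairs, with fewer samples in the fit, called 610 genes between the gates there, and DNA repair genes (0.144, adjusted p = 0.111) and other antioxidant enzymes (-0.18, adjusted p = 0.0817) were not called. A fixed block over all 3 pairs gave 6 genes, for a difference between gates averaged over 2 knockout pairs and 1 wild-type pair, which is not a wild-type effect. Ttk stood there at -0.10 and the median of G2 and M phase genes at 0.0147, and the mean of these genes differed by 0.37 in the wild-type pair and by -0.27 and -0.07 in the knockout pairs. Averaging several probe sets per gene was not run, since each gene had 1. Signal over background was not analysed here, as the table holds no detection calls.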

Other observations

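The averaged knockout effect and the test of the neighbours of Atg7 were added after the comparisons had been seen, and the threshold of the neighbour test was set before its result was known.

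Averaged over both gates, 4 of 15873 genes differed between knockout and wild type by limma. This average treats samples that share a title number as independent. Tdg-ps2, a pseudogene related to the thymine DNA glycosylase gene Tdg, fell by 1.63 (SE 0.19, adjusted p = 0.00789) and was lower on each of the 7 knockout arrays than on any of the 7 wild-type arrays. Its probes can also read closely related copies. Ang4, the antimicrobial gene of Paneth cells, fell by 1.87 (SE 0.26, adjusted p = 0.0239), and Pxdn fell by 0.89 (SE 0.13, adjusted p = 0.0299). Gm12292 rose by 0.84 (SE 0.11, adjusted p = 0.0117) in this average, over differences of 2.01 in EGFP high and -0.33 (SE 0.14, adjusted p = 0.665) in EGFP low cells. Atg7 had a difference of -0.84 (SE 0.15, adjusted p = 0.157). At an unadjusted p under 0.05 there were 1587 genes.

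Over the 28 lists 10 were called, at adjusted p between 0.616 and 0.781 with an estimated correlation. The averaged effect was lowest for goblet (median -0.43) and Paneth markers (-0.41), which were called together with G2 and M phase genes (-0.24), S phase genes (-0.22), enterocyte markers (-0.21), unfolded protein response genes (-0.21), antigen presentation genes (-0.18), DNA repair genes (-0.13) and autophagy genes (-0.12). Reserve and regenerative stem cell markers were called higher, with a median of 0.12. In EGFP high cells their mean level was 5.34 in Atg7KO-High-348, against 4.94 and 4.98 in the other knockout samples. In wild type it was 4.92 to 5.01 there. In EGFP low cells it was 5.00 to 5.28 in the knockout and 4.96 to 5.01 in wild type. For some of the 10 called lists the average joins medians of opposite sign in EGFP high and EGFP low cells. These were antigen presentation genes (-0.58 and 0.20), S phase genes (-0.49 and 0.09) and enterocyte markers (-0.49 and 0.05). Medians of the other called lists had the same sign in both gates.

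A hypothesis was that DNA of another strain, carried along with the floxed allele, may make genes next to Atg7 differ between the genotypes. Among the 100 tested neighbours, 50 on each side in the gene order of the GRCm38.p6 annotation, 12% had a p under 0.05 in the averaged effect. Other windows of the same size had a median of 10%, and 16% bounded their central 95% from above, so the test decides neither way. Strain background was not given in the sources used here.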
